A study of Mus musculus with 21 samples.

How the data were processed

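Cerebral cortex of 21 mice was measured on Affymetrix MOE430A 2.0 arrays, with 1 array for each mouse. The mice came from 2 lines with a doxycycline-controlled transgene for human TDP-43, an RNA-binding protein. Line WT12 encodes the wild-type protein and line NLS4 a protein with a defective nuclear localization signal, called dNLS here. The transgene is driven by tTA, a transactivator that doxycycline in the diet keeps inactive, and the tissue was taken 2 weeks after the diet was withdrawn. Total RNA was extracted with TRIzol and labelled with biotin after 1 round of linear amplification primed from the poly(A) tail, per the labels.

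The values are log2 levels of 22690 probe sets as deposited. The base of the logarithm is not named in the labels and was read from the values, which ran from 2.04 to 15.1, the span of a 16-bit scanner on that scale. Partek is named in the submitters' notes without a version or a role. The methods of background correction, normalization and summarization are not given in the sources used here. A common lowest value of 2.04 was held by 30.7% to 32.4% of the probe sets of an array. Changes toward that value are compressed. The number of arrays limits the precision.

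Probe sets were assigned to genes with the supplied table of probe genes, and symbols were compared with the RefSeq table of assembly GRCm38.p6 through Entrez identifiers, of which 20364 matched and 29 did not. No symbol changed. After 64 control probe sets were set aside, 20393 probe sets named 1 symbol, 691 named several and 1555 named none. The last 2 classes were not used in the comparisons. Each of the 12394 genes was represented by its probe set of highest mean over the 21 arrays, which involved a choice for 4958 genes. On all 21 arrays, 2854 genes lay at the lowest value and 8367 above it, with a tolerance of 0.01. The 2854 genes stayed in the main comparisons and count among the measured members of a list, although no change can be seen in them.

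Groups followed the titles, genotypes, lines and sexes in the labels. They were 5 dNLS bigenic mice with both transgenes, 4 dNLS monogenic mice with the TDP-43 transgene alone, 4 WT bigenic mice and 8 nontransgenic mice of both lines. No group carried tTA alone. An effect of tTA itself was thus not separated from that of TDP-43 where bigenic mice were compared with nontransgenic or dNLS monogenic mice.

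A linear model with the 4 groups and sex as a covariate was fitted to all 21 arrays in limma 3.58.1 under R 4.3.3, with lmFit and eBayes and an intensity trend. The p-values were adjusted by the Benjamini-Hochberg method over the 12394 genes, and an adjusted p of 0.05 was the threshold. Standard errors are those of the moderated fit. The comparison of nontransgenic mice of both lines used 5 groups, and the interaction of sex with the dNLS transgene added that term. Per-array degradation was measured as the difference between 3' and 5', or 3' and middle, control probe sets of beta-actin and Gapdh, and groups were compared by two-sided exact permutation tests with Benjamini-Hochberg adjustment over the 5 comparisons of a measure. Sex labels were checked with Xist and the Y-linked genes. Principal components were taken over all genes.

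There were 36 gene lists. They held the target gene, sex label check genes, tTA insertion locus, histone genes, pan-neuronal, excitatory neurons, upper layers, deep layers, interneurons, astrocytes, reactive astrocytes, microglia, activated microglia, oligodendrocytes, oligodendrocyte precursors, endothelium and mural cells, choroid plexus, striatum, hippocampus, thalamus, meninges, blood, activity-regulated genes, integrated stress and ER stress, p53 targets, heat shock, interferon response, MHC class I and antigen processing, glutamate receptors and synapse, voltage-gated channels, long-intron neuronal genes, RNA-binding proteins, ALS and FTD genes, oxidative phosphorylation, ribosomal proteins and cholesterol synthesis. The groups, comparisons, lists, rule for named genes and first set of alternatives were chosen before the data were examined. The histone list was chosen knowing that the study discusses histone genes. The tTA insertion locus was taken from general knowledge and not from a supplied file, and 2 of its presumed genes, Wdr60 and Esyt2, had no probe set under these symbols. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. The camera test compares a list with the other genes, whereas fry asks if the list moves on balance. A second adjustment ran over the genes of each list alone.

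The rule for named genes took, in each comparison, the 12 largest increases and the 12 largest decreases among genes past the threshold, the 4 largest changes past it in each list, and always Tardbp, the sex genes and the genes of the tTA insertion locus. The text names part of these genes and gives the others as counts. Genes outside the rule are marked where they stand.

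The log2 fold changes of both bigenic groups share their controls, so their correlation across genes was set against 100 simulations of unchanged groups and against a fit with separate controls for each line. Simulations under the other settings, and of the sign agreement, were added after seeing the data. For each of 5 comparisons and for sex, the arrays were also split in up to 100 ways into groups of the same sizes, with a fixed seed. The pipeline was tested on simulated data at the group sizes of each comparison. In them 200 of 12394 genes were given a log2 change of 0.5, 1 or 2. Their noise was independent between genes and of equal spread on all arrays. The changed genes were drawn from those above the lowest value on every array. The rates found may therefore be too favourable for the real arrays.

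Alternatives were an adjusted p threshold of 0.01, a minimum of 1.5-fold, no sex covariate, quantile normalization and centring of each array on its median. Further ones were a filter for genes above the 40th percentile on at least 4 arrays, every probe set and probe sets without a suffix preferred. No intensity trend, no variance moderation, array weights, only the compared groups, controls of the same line and a single sex were also used. Single arrays were left out in turn, all 21 for sex and otherwise only those of the groups compared. Alternatives chosen after seeing the data were a beta-actin covariate, leaving out the 2 nontransgenic arrays with the largest beta-actin difference, leaving out genes at the lowest value on every array, and sex as read from Xist. Figures were drawn with matplotlib 3.10.9, and tables were assembled with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15. No chromosomal positions are reported, since the RefSeq table served for names and gene order only.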

Results

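Gene expression in the cerebral cortex was measured in 21 mice, 5 of them dNLS bigenic, 4 dNLS monogenic, 4 WT bigenic and 8 nontransgenic. The dNLS bigenic group held 4 males and 1 female, the dNLS monogenic group 3 males and 1 female, and the WT bigenic group 1 male and 3 females by label. The nontransgenic group held 4 males and 2 females of line NLS4 and 2 females of line WT12. The median log2 level of an array lay between 5.76 and 6.05. The genotypes were compared to see what TDP-43 that is held out of the nucleus, and wild-type TDP-43 at raised level, do to the expression of other genes.

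The 3' bias of control probe sets, taken here as a measure of RNA quality, differed between arrays. The labels give a minimum RIN, a score of RNA integrity, of 7 for every sample. Degradation was thus not told apart from bias that arose in amplification or labelling. Arrays called degraded here are those with the largest bias. The beta-actin 3' minus 5' difference, which grows as RNA breaks down, averaged 3.18 ± 2.31 (SD, n = 8) log2 units in nontransgenic, 2.00 ± 0.76 (n = 4) in dNLS monogenic, 1.39 ± 0.03 (n = 4) in WT bigenic and 1.75 ± 0.35 (n = 5) in dNLS bigenic arrays. Nontransgenic 6, at 8.20, and nontransgenic 4, at 4.70, had the highest values, and their scores on the first principal component, which held 38.9% of the variance, were 89.2 and 42.0. By two-sided exact permutation tests the beta-actin difference did not differ past the threshold for dNLS bigenic against nontransgenic (p = 0.208, adjusted p = 0.346), WT bigenic against nontransgenic (p = 0.115, adjusted p = 0.288) or dNLS bigenic against WT bigenic (p = 0.0794, adjusted p = 0.288). The Gapdh 3' minus middle difference was lower in dNLS bigenic than in dNLS monogenic arrays (exact permutation p = 0.00794, adjusted p = 0.0397). The second component, with 19.3% of the variance, lay between 18.6 and 35.2 in the dNLS bigenic arrays and between -19.6 and 10.8 in all others.

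**Figure D1:**
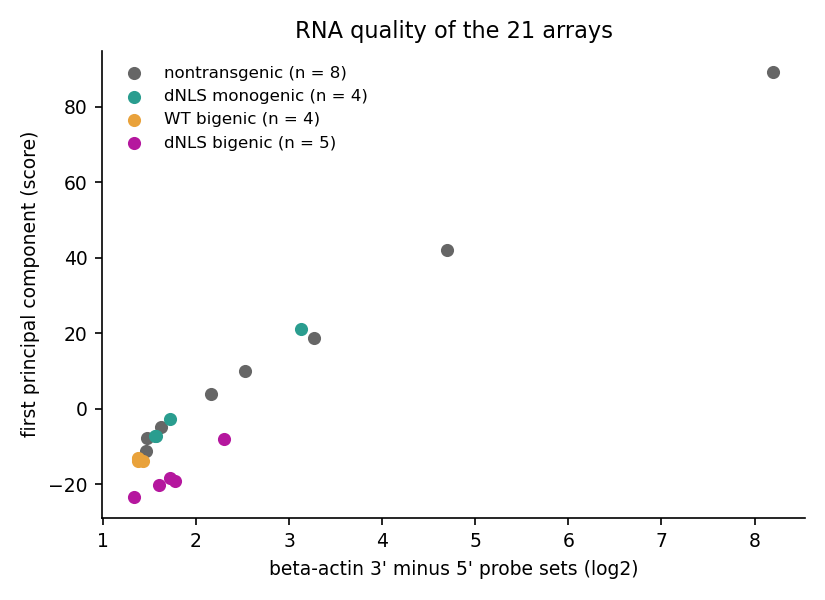
First principal component score of each of the 21 arrays against its beta-actin 3' minus 5' difference in log2 units, coloured by group. Nontransgenic 6 lies at 8.20 and 89.2, apart from the other arrays.

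Xist, the transcript of the inactive X chromosome, was read on all 9 arrays labelled female, and Y-linked genes on 11 of the 12 labelled male. Nontransgenic 1, labelled male, read as female, with Xist at 11.97 and Eif2s3y at the lowest value of 2.04. The label was kept in the model, and the counts with sex as read from Xist are given with the comparisons they move most.

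The 4 probe sets of Tardbp, the mouse gene for TDP-43, moved in different directions in dNLS bigenic mice. No probe sequences were available to say which parts of the transcript they read, or if they read the human transgene, so a change of the mouse gene as a whole cannot be given. The probe set of highest mean fell by 0.23 ± 0.07 (SE, adjusted p = 0.0213) on the log2 scale against nontransgenic, from 11.11 ± 0.13 (SD, n = 8) to 10.90 ± 0.13 (n = 5). The probe set second in mean fell by 1.32 ± 0.09, with all 5 dNLS bigenic arrays below all others, while the dimmest rose by 1.11 ± 0.19 (adjusted p = 3.4e-04 over every probe set) and the third did not pass, at -0.43 (adjusted p = 0.303). The call for the first probe set rested on single mice, since its adjusted p was 0.0602 without dNLS bigenic 4 and 0.120 without dNLS bigenic 5. For that probe set the change in WT bigenic mice was -0.05 (adjusted p = 0.862) and in dNLS monogenic mice -0.05 (adjusted p = 1), and neither passed the test. The direct difference between both bigenic groups was -0.18 (adjusted p = 0.218).

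**Figure D2:**
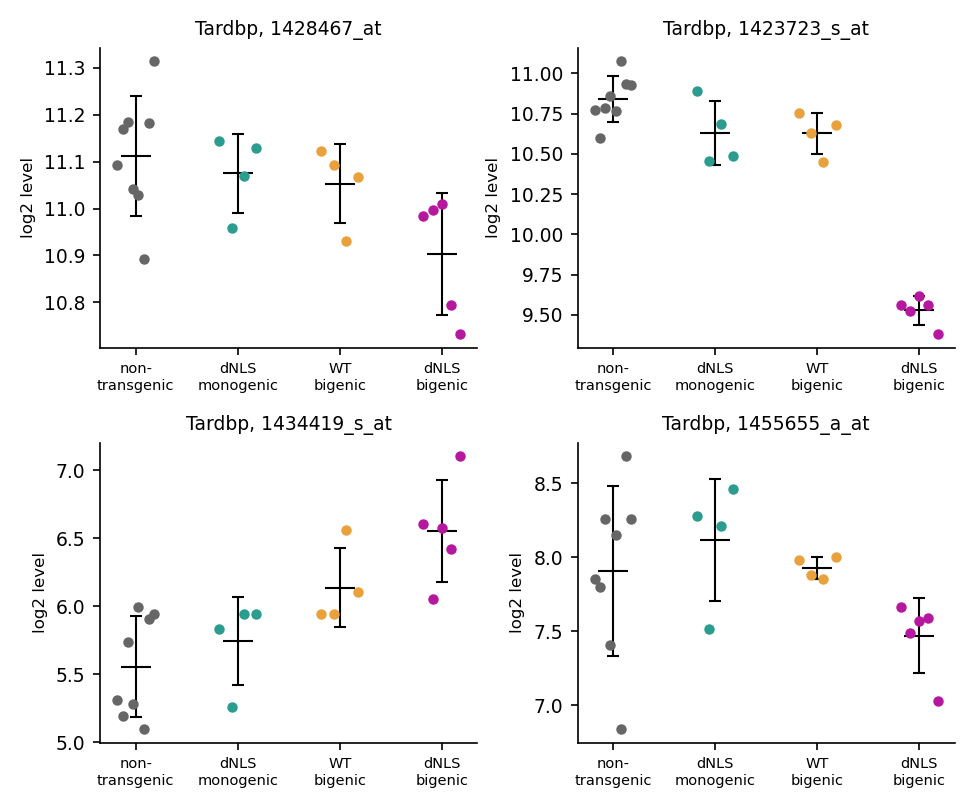
Log2 levels of 4 Tardbp probe sets per array by group, with the mean and SD of each group. For the probe set second in mean the 5 dNLS bigenic arrays lie below the other 16, and for the dimmest the dNLS bigenic mean is the highest.

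Mice with dNLS TDP-43 were set against nontransgenic mice to ask what the cytoplasmic protein does. Spag5, a mitotic spindle protein, had the largest decrease, at 27.8-fold with a log2 change of -4.79 ± 0.31 (SE, n = 5 against 8, adjusted p = 2.3e-08). Egr2, an activity-induced transcription factor, changed by -4.38 ± 0.67, and Otof, Myh7, Myh1, Susd2, Ddit4l, Abi3bp, Tchh, Smoc2, Pkp2 and Rnf207 by -4.27 to -3.03. Among them Myh7 and Myh1 encode myosin heavy chains, Otof the hair-cell protein otoferlin and Pkp2 a desmosome protein. The largest increases were in Tnfrsf12a, the receptor of the cytokine TWEAK, at 9.11-fold with 3.19 ± 0.26 (adjusted p = 1.9e-07), and in Pmaip1, a pro-apoptotic p53 target, at 3.15 ± 0.58. Dach2, Zfp54, Mettl27, Etaa1, Rpp40, Cars, Gla, Opn3, Alg3 and Hilpda rose by 3.01 to 2.25.

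In this comparison 2759 of 12394 genes passed the threshold, 1336 higher and 1423 lower in dNLS bigenic mice, and 202 and 217 of them by at least 2-fold. Of the 72 named genes past the threshold, 71 had all 5 dNLS bigenic arrays on the side of the change from the nontransgenic mean, with 4 of 5 for Atf3. These genes were chosen for their change, so this is no further test of it. In most nontransgenic arrays Dach2, Zfp54, Mettl27 and Atf3 lay near the lowest value, with group means of 2.58, 2.21, 2.53 and 2.07, so their increases may be compressed. Dach2 was at 5.29 in nontransgenic 6. The mean level of Otof, Myh1, Susd2 and Rnf207 in dNLS bigenic arrays lay between 2.15 and 2.39, near the lowest value, so their decreases are compressed. The share of changes that were increases was 48.4%, and 35.9% of 2710 genes when arrays were centred on their medians, which moved the median gene by -0.08 on the log2 scale. Without single arrays the count lay between 2365 and 3316. In simulated data for these groups, 38.8% of changes of 0.5, 76.1% of changes of 1 and 98.5% of changes of 2 log2 units were found, with 5.33% false calls.

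**Figure D3:**
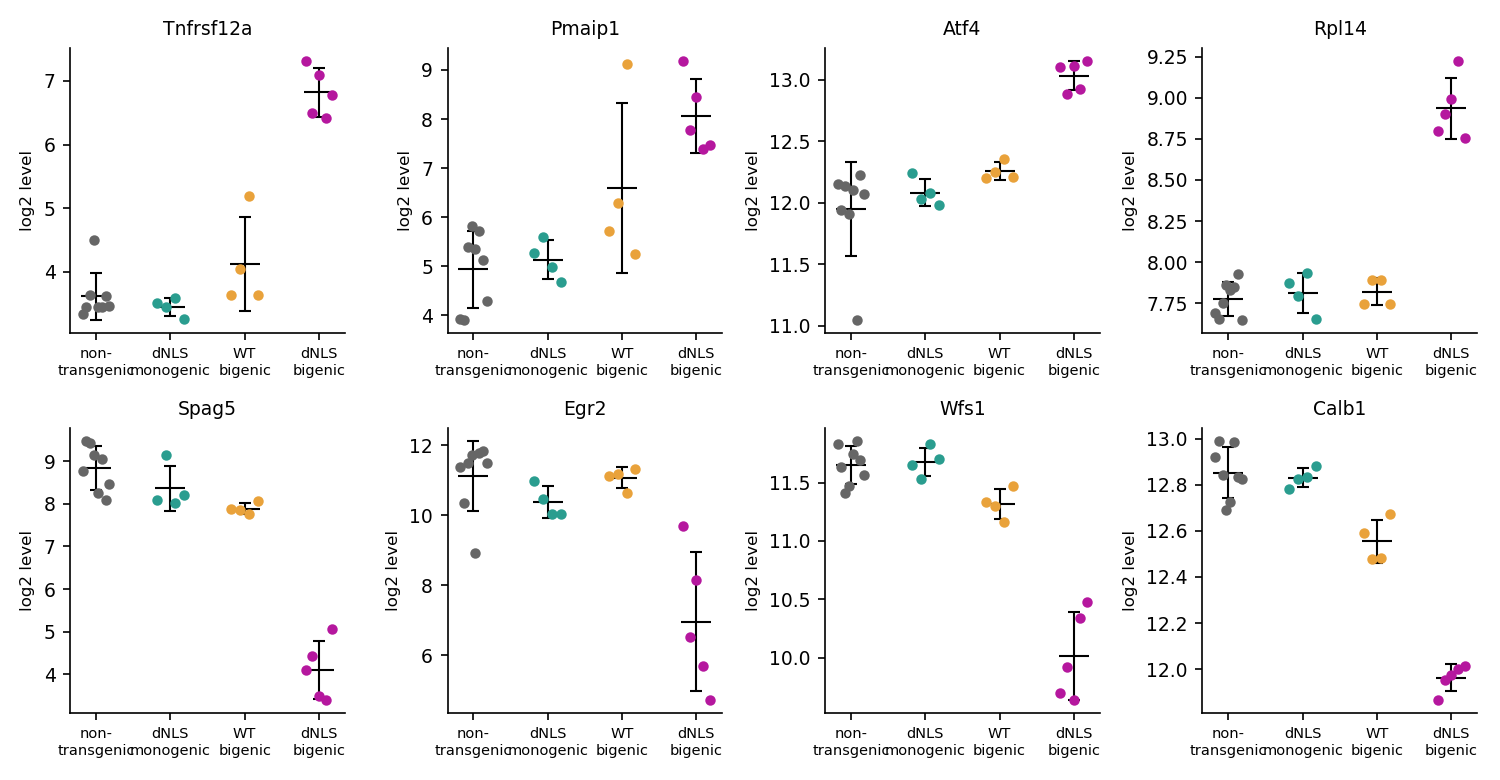
Log2 levels of 8 genes per array by group, with the mean and SD of each group. Tnfrsf12a and Rpl14 are higher and Spag5, Wfs1 and Calb1 lower in all 5 dNLS bigenic arrays than in any other array.

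Neuronal genes moved apart in dNLS bigenic cortex. Among excitatory neuron genes Slc17a6, a vesicular glutamate transporter, fell by 1.54 ± 0.13 on the log2 scale and the probe set of highest mean of Mef2c, a transcription factor, by 0.18 ± 0.04, while Rtn4r, a receptor of myelin inhibitors, rose by 0.55 ± 0.13. The other 4 Mef2c probe sets did not pass and went both ways, at -0.09, -0.08, 0.10 and 1.31. That list had 1 gene up and 3 down of 9 measured. Adjusted over the list alone, 1 was up and 5 down. In the upper layers list Calb1, a calcium buffer, fell by 0.89 ± 0.05 (adjusted p = 1.1e-08) and Cux1, a layer-specific transcription factor, by 0.70 ± 0.14, with 0 up and 2 down of 8, and the same counts adjusted over the list alone. In the deep layers list Crym, a thyroid hormone binding protein, fell by 1.02 ± 0.15 and Tle4, a corepressor, by 0.30 ± 0.07, with 0 up and 3 down of 10, also adjusted over the list alone. In the pan-neuronal list Thy1 rose by 0.34 ± 0.04 and Nefl, the light neurofilament, fell by 0.45 ± 0.07, with 4 up and 1 down of 14, and 4 up and 3 down adjusted over the list alone. Interneuron genes had 2 up and 3 down of 15, the same adjusted over the list alone. Npy rose by 0.34 ± 0.06, and Sst and Reln, a peptide and a matrix protein, fell by 0.44 ± 0.12 and 0.51 ± 0.11. None of these 5 lists passed camera (adjusted p from 0.0952 for excitatory neurons to 0.521 for interneurons), and adjusted p = 0.512 or more with an estimated correlation.

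Of 21 genes in the lists of neighbouring regions 6 passed. In the hippocampus list Wfs1, an endoplasmic reticulum protein, fell by 1.58 ± 0.12 and Neurod1, a neuronal transcription factor, by 1.21 ± 0.11. It had 1 gene up and 3 down of 8, also adjusted over the list alone, with a camera adjusted p = 0.0801 and adjusted p = 0.367 with an estimated correlation. Calb1 belongs to this list as well as to the upper layers list. In the thalamus list Rora, a nuclear receptor, rose by 0.84 ± 0.12, the only change of 6 genes, also adjusted over the list alone, at a camera adjusted p = 0.763. In the striatum list Penk, which encodes enkephalin, fell by 1.61 ± 0.51, the only change of 7, also adjusted over the list alone, at a camera adjusted p = 0.577. The adjusted p of Penk was 0.0778, 0.0616 and 0.0690 without dNLS bigenic 1, 2 and 3, and 0.0591 without nontransgenic 1. The thalamus list had an adjusted p = 0.861 with an estimated correlation, and the striatum list 0.868.

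Activity-regulated genes had 0 up and 5 down of 17 measured, and 1 up and 5 down adjusted over the list alone. Besides Egr2, Nptx2, a synaptic pentraxin, fell by 1.87 ± 0.37 and Arc, a synaptic plasticity gene, by 1.71 ± 0.56. Camera gave an adjusted p = 0.0779, and adjusted p = 0.845 with an estimated correlation. The adjusted p of Arc was 0.0699, 0.103 and 0.103 without dNLS bigenic 2, 4 and 5, and 0.0676, 0.0701, 0.0630, 0.0517 and 0.0519 without nontransgenic 1, 3, 4, 7 and 8. It was also 0.0651 with controls of the same line.

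Stress genes moved both ways. In the integrated stress and ER stress list Chac1, a glutathione-degrading enzyme, rose by 1.43 ± 0.40, the transcription factor Atf4 by 1.07 ± 0.15, and the chaperone Creld2 fell by 1.17 ± 0.29. The list had 7 up and 2 down of 19, and 7 and 3 adjusted over the list alone (camera adjusted p = 0.189, adjusted p = 0.845 with an estimated correlation). Among p53 targets Pmaip1, Aen, a nuclease, at 1.51 ± 0.18, and Phlda3, an inhibitor of AKT, at 0.81 ± 0.23 rose, and Sesn1, a sestrin, fell by 0.61 ± 0.16. That list had 3 up and 3 down of 16, and 5 and 4 adjusted over the list alone (camera adjusted p = 0.715, adjusted p = 0.861 with an estimated correlation). Heat shock genes had 0 up and 3 down of 14, and 1 up and 7 down adjusted over the list alone, and Dnaja1, a chaperone partner, fell by 0.59 ± 0.05 (camera adjusted p = 0.0779, adjusted p = 0.659 with an estimated correlation). Atf3, a transcription factor, passed at 1.14 ± 0.28, with measured means of 2.07 and 3.11, and 7 of 8 nontransgenic arrays lay at the lowest value, as nearly did dNLS bigenic 2 and 4. Without dNLS bigenic 5 the adjusted p was 0.0564 for Atf3, 0.0608 for Chac1, 0.0944 for Phlda3 and 0.0621 for Sesn1.

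The ribosomal protein list was the only one of 36 past camera in this comparison (adjusted p = 2.7e-07), a call lost at adjusted p = 0.273 with an estimated correlation. More lists passed by fry, which asks if a list moves on balance. They are not named here, and their count is given with the other ways of processing. Rpl14 rose by 1.15 ± 0.08 (adjusted p = 3.7e-08), Rps19 by 0.85 ± 0.23 and Rplp0 by 0.66 ± 0.09, and the list had 24 up and 1 down of 47, and 26 and 1 adjusted over the list alone. The median change was 0.16 on the log2 scale, and 0.07 with arrays centred on their medians, which left 16 up and 3 down. Oxidative phosphorylation genes had 16 up and 8 down of 76, and 18 and 8 adjusted over the list alone, but 5 up and 14 down with centred arrays, which turned the median from 0.01 to -0.08 (camera adjusted p = 0.197, adjusted p = 0.845 with an estimated correlation). Atp5g1 rose by 0.69 ± 0.09 and Atp5l fell by 0.43 ± 0.05, both subunits of the ATP synthase. The number of lists past camera was 6 without dNLS bigenic 1, 5 without dNLS bigenic 3, 3 without nontransgenic 2, 4 or 6, and 2 without dNLS bigenic 2 or 4 or nontransgenic 1.

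RNA-binding protein genes had 1 up and 8 down of 30, and 1 and 11 adjusted over the list alone. Nova1, a neuronal splicing factor, fell 5.03-fold, by 2.33 ± 0.27 on the log2 scale, the probe set of highest mean of Elavl4, a neuronal RNA stabilizer, by 0.61 ± 0.08 and Hnrnpd by 0.59 ± 0.10 (camera adjusted p = 0.0645, adjusted p = 0.512 with an estimated correlation). The other 2 Elavl4 probe sets did not pass, at -0.44 and 0.14. Genes linked to ALS and FTD had 2 up and 4 down of 17, also adjusted over the list alone. C9orf72 rose by 0.78 ± 0.12 and Ubqln2, a proteasome shuttle, fell by 0.50 ± 0.08 (camera adjusted p = 0.625, adjusted p = 0.845 with an estimated correlation). Cholesterol synthesis genes had 0 up and 5 down of 15, and 0 and 6 adjusted over the list alone. The enzymes Fdft1 and Sqle fell by 1.09 ± 0.12 and 0.84 ± 0.14 (camera adjusted p = 0.0645, adjusted p = 0.815 with an estimated correlation). Histone genes had 3 up and 3 down of 14, and 4 and 3 adjusted over the list alone. This list is not independent evidence because it was chosen knowing the study. Outside it were 9 probe sets that name several genes, at least 1 of them a histone. The counts do not cover these, so they do not describe the histone genes as a whole. H2ac19 rose by 0.67 ± 0.15 and H2az2, a variant histone, fell by 0.79 ± 0.19, and centred arrays gave 1 up and 3 down (camera adjusted p = 0.642, adjusted p = 0.845 with an estimated correlation). Long-intron neuronal genes, described elsewhere as lowered when TDP-43 is depleted, had 0 up and 3 down of 15, and 0 and 4 adjusted over the list alone (camera adjusted p = 0.521, adjusted p = 0.845 with an estimated correlation). Voltage-gated channel genes had 1 up and 2 down of 16, also adjusted over the list alone, and Scn3b, a sodium channel subunit, fell by 0.58 ± 0.10 (camera adjusted p = 0.577, adjusted p = 0.859 with an estimated correlation). Glutamate receptor and synapse genes had 1 up and 1 down of 12, also adjusted over the list alone (camera adjusted p = 0.831, adjusted p = 0.932 with an estimated correlation).

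Glial genes changed little in number. Of 12 astrocyte genes 1 was down and 0 up, also adjusted over the list alone, and Aldh1l1, a folate enzyme of astrocytes, fell by 0.47 ± 0.12 (camera adjusted p = 0.246, adjusted p = 0.845 with an estimated correlation). Of 15 reactive astrocyte genes 1, the protease inhibitor Serpina3n, was up, by 2.12 ± 0.39, and 0 were down, also adjusted over the list alone. Camera gave this list an adjusted p = 0.856, and adjusted p = 0.932 with an estimated correlation. Its median change was 0, as for genes at the lowest value, so the count does not show that the other members were unchanged. Microglia genes had 0 up and 3 down of 18, also adjusted over the list alone. Gpr34 and Tmem119, surface proteins of resting microglia, fell by 1.04 ± 0.30 and 0.61 ± 0.15 (camera adjusted p = 0.0983, adjusted p = 0.845 with an estimated correlation), and the adjusted p of Gpr34 was 0.0576 without dNLS bigenic 5. Activated microglia genes had 1 up and 1 down of 20, also adjusted over the list alone. Ctsd, a lysosomal protease, rose by 0.69 ± 0.15 and Lpl, a lipase, fell by 1.22 ± 0.29 (camera adjusted p = 0.831, adjusted p = 0.932 with an estimated correlation). Oligodendrocyte genes had 0 up and 2 down of 10 and their precursor genes 0 up and 1 down of 5, both also adjusted over the list alone, at camera adjusted p of 0.763 and 0.253, with adjusted p = 0.932 and adjusted p = 0.845 with an estimated correlation.

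The remaining lists held few or no changes between dNLS bigenic and nontransgenic mice. Members at or near the lowest value of 2.04 could hide a change, so a count of 0 does not show its absence. The interferon response list, for one, had a mean level of 3.59 in dNLS bigenic and 3.83 in nontransgenic arrays. Of 11 meninges genes 0 were up and 1 was down, and 0 changed adjusted over the list alone (camera adjusted p = 0.378, adjusted p = 0.845 with an estimated correlation). With limma, 0 genes passed in the lists of endothelium and mural cells, choroid plexus, blood, interferon response, MHC class I and antigen processing, and sex label check, of 14, 8, 6, 14, 8 and 4 measured, and 0 adjusted over the list alone. Camera gave adjusted p of 0.285, 0.386, 0.902, 0.740, 0.538 and 0.763 for them, and adjusted p = 0.845 or more with an estimated correlation. The list named for the tTA insertion locus, a site taken from general knowledge, had 0 changes of 3, and 1 down adjusted over the list alone (camera adjusted p = 0.567, adjusted p = 0.845 with an estimated correlation), with Ncapg2 at -1.54 ± 0.56 (adjusted p = 0.0574) and Ptprn2 at -0.28 ± 0.24 (adjusted p = 0.510). The target gene list, Tardbp alone, had 1 down of 1, by the probe set of highest mean, and a camera adjusted p = 0.378.

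**Figure D4:**
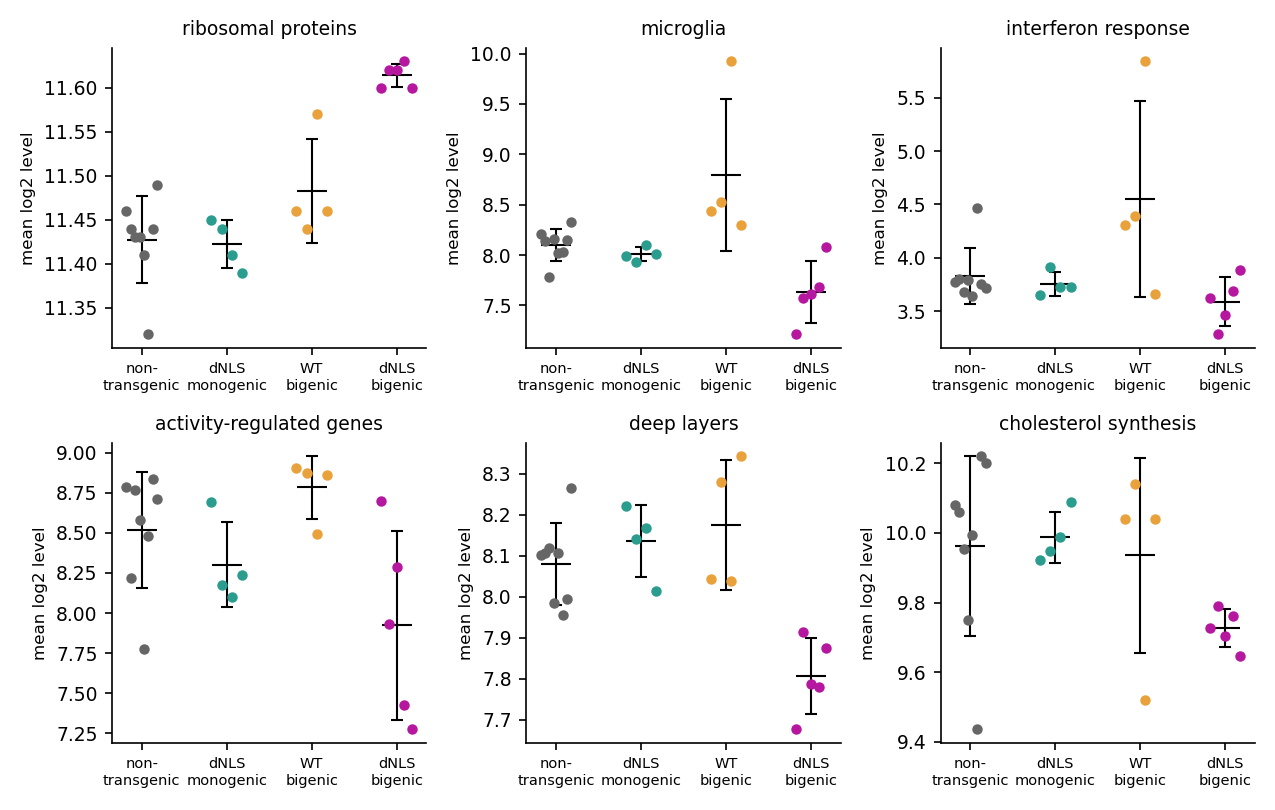
Mean log2 level of 6 gene lists per array by group, with the mean and SD of each group. WT bigenic 3 is the highest array for microglia, at 9.92, and for interferon response.

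WT bigenic mice, which carry the wild-type protein, showed fewer changes against nontransgenic mice. Ncapg2, a condensin subunit, had the largest decrease, at 11.6-fold with a log2 change of -3.53 ± 0.59 (SE, n = 4 against 8, adjusted p = 0.0133). Susd2 and Otof fell by 2.76 ± 0.42 and 2.66 ± 0.54, and Gm29722, Myh7, Trpc6, Cdh9, Ngb, Pisd-ps3, Lipg, Rgs16 and Gask1b fell by 1.99 to 1.52. Among them Trpc6 encodes a cation channel, Cdh9 a cadherin, Ngb neuroglobin and Lipg endothelial lipase. Slc17a6, Reln and Calb1 fell by 0.95 ± 0.14, 0.72 ± 0.12 and 0.30 ± 0.06, and Nova1 by 1.15 ± 0.28. The largest increases were in Fcgr1, a high-affinity antibody receptor of microglia, at 1.62 ± 0.33, Tex261 at 1.14 ± 0.27, Id1, a transcription inhibitor, at 1.11 ± 0.23, and Fcgr3, another antibody receptor, at 1.01 ± 0.24. Rpf1, Fxyd1, Blvrb, Gadd45g, Fkbpl, Psmg3, Eps8l3 and Fbxo2 rose by 1.00 to 0.71.

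In all, 276 genes passed, 85 higher and 191 lower in WT bigenic mice, with 4 and 31 of them by at least 2-fold. All 4 WT bigenic arrays lay on the side of the change for each of the 28 named genes, which were chosen for their change. Simulated changes of 0.5, 1 and 2 log2 units were found in 41.8%, 74.6% and 97.0% of cases for these groups, with 4.70% false calls. Against the 2 nontransgenic females of the same line 1 gene passed, and 0 of the 276 genes were called, although all 276 kept their sign at a median of 0.905 of their size. The count was 413 with sex as read from Xist, 163 with a beta-actin covariate, which kept 113 of the 276 calls and the sign of all at a median of 0.796 of their size, and 4965 with centred arrays, a scaling that moved the median gene by -0.113 and left 4.55% of changes as increases.

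Single arrays decided many of these calls. The count was 37, 60, 38 and 116 without WT bigenic 1, 2, 3 and 4, and 182, 579 and 139 without nontransgenic 2, 5 and 7. Of the 28 named genes, 20 lost their call when some array was left out. Without WT bigenic 1 there were 18 such genes, with adjusted p from 0.0514 to 0.194, without WT bigenic 2 there were 13, from 0.0544 to 0.105, without WT bigenic 3 there were 17, from 0.0561 to 0.167, and without WT bigenic 4 there were 9, from 0.0501 to 0.0935. Without nontransgenic 2, 3, 4, 6 and 7 there were 4, 5, 2, 2 and 4, with adjusted p up to 0.0748, and without nontransgenic 1 only Myh7, at 0.0580. Susd2, Trpc6, Pisd-ps3, Slc17a6, Reln, Rpf1, Fxyd1 and Blvrb kept theirs without each array of these groups.

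Camera passed 5 lists in WT bigenic against nontransgenic mice, 4 of them of microglial, interferon and MHC genes, and each call was lost at adjusted p = 0.555 with an estimated correlation. Microglia genes had 1 up, Fcgr3, and 0 down of 18, and 5 and 0 adjusted over the list alone, with a median change of 0.45 on the log2 scale (camera adjusted p = 8.0e-06). Activated microglia genes had 0 changes of 20, and 2 up adjusted over the list alone, with a median of 0.54 (camera adjusted p = 1.2e-05). Interferon response genes had 0 changes of 14, and 6 up adjusted over the list alone, with a median of 0.54 (camera adjusted p = 8.0e-06). Genes of MHC class I and antigen processing had 0 changes of 8, and 2 up adjusted over the list alone, with a median of 0.23 (camera adjusted p = 4.1e-04). Ribosomal protein genes had 0 up and 1 down of 47, also adjusted over the list alone, and camera called them up at a median of 0.05 (adjusted p = 3.0e-04), which turned to -0.06 with centred arrays. With centred arrays the medians of the other 4 lists, in the order above, were 0.33, 0.43, 0.42 and 0.12. Fry passed none of these 5 lists. Without WT bigenic 3 the medians were 0.22 for microglia, 0.06 for activated microglia, 0.20 for interferon response and 0.14 for MHC class I genes, and camera still passed each of them.

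The direct comparison of dNLS bigenic with WT bigenic mice asks which changes differ between both transgenes. Hcn3, a pacemaker channel, was higher in dNLS bigenic mice by a fitted log2 difference of 2.38 ± 0.17 (SE, n = 5 against 4, adjusted p = 5.4e-07). Its measured means were 4.59 and, near the lowest value, 2.21, so the difference may be compressed. Myo7a, a myosin, Eif4ebp1, a translation inhibitor, and Mtfr1 were higher by 2.38 ± 0.43, 2.33 ± 0.67 and 2.30 ± 0.38. Ccn1, a matrix protein, was lower, at -2.99 ± 0.61, as were Echdc2 at -2.60 ± 0.38, Btg2, an activity and p53 target, at -2.43 ± 0.71, and Tnnc1, a troponin, at -2.34 ± 0.21. Of 12394 genes 1334 passed, 773 higher and 561 lower in dNLS bigenic mice, 145 and 92 of them by at least 2-fold. All 5 dNLS bigenic arrays lay on the side of the difference in each of the 18 named genes, which were chosen for it. The sexes are uneven here, with 4 of 5 dNLS bigenic and 1 of 4 WT bigenic mice male. Simulated differences of 0.5, 1 and 2 log2 units were found in 43.3%, 67.2% and 95.5% of cases, with 4.20% false calls.

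In this comparison 10 lists passed camera, 9 of them lower in dNLS bigenic mice, and all 10 calls were lost with an estimated correlation, the lowest being hippocampus at adjusted p = 0.225 with an estimated correlation. Microglia genes had 0 up and 7 down of 18, and 0 and 13 adjusted over the list alone (adjusted p = 7.7e-08), with Olfml3, a secreted glycoprotein, at -1.82 ± 0.43 and Tyrobp, a microglial adaptor, at -1.12 ± 0.28. Interferon response genes had 0 up and 4 down of 14, and 0 and 5 adjusted over the list alone (adjusted p = 2.5e-04), with Bst2, an antiviral tether, at -2.17 ± 0.63 and Ifit1 at -1.71 ± 0.52. Activated microglia and meninges genes had 0 changes of 20 and 11, also adjusted over the list alone (adjusted p = 0.00338 and 0.0261). Activity-regulated genes had 0 up and 6 down of 17, and 0 and 8 adjusted over the list alone (adjusted p = 2.8e-04), with Fos at -1.41 ± 0.42. Deep layers genes, with Crym at -1.18 ± 0.18, had 0 up and 2 down of 10, and 0 and 3 adjusted over the list alone, and hippocampus genes, with Wfs1 at -1.21 ± 0.15, 0 up and 3 down of 8, also adjusted over the list alone (both adjusted p = 0.0114). Astrocyte genes had 0 up and 1 down of 12, and 0 and 2 adjusted over the list alone (adjusted p = 0.0114), and heat shock genes 0 up and 1 down of 14, also adjusted over the list alone (adjusted p = 0.0480). Ribosomal protein genes, with Rpl14 at 1.10 ± 0.10, had 6 up and 0 down of 47, also adjusted over the list alone (adjusted p = 5.7e-04). In the integrated stress list, which did not pass, Chac1 was higher by 2.13 ± 0.49 and Atf5, a stress transcription factor, by 0.98 ± 0.21.

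With each line's own nontransgenic mice as controls the count for this difference was 440, of which 392 were among the 1334. Of the 1334 genes 1333 kept their sign, at a median of 0.937 of their size, while the WT12 controls shrank to 2 mice. Without WT bigenic 1 it was 817. Of the named genes Atf5 lost its call without WT bigenic 1 (adjusted p = 0.0507), Bst2 without dNLS bigenic 1, 2 or 3 or WT bigenic 1, 2 or 3 (0.0606 to 0.0769), and Btg2 without dNLS bigenic 2, 4 or 5 or WT bigenic 1, 2 or 4 (0.0533 to 0.319). Eif4ebp1 lost it without dNLS bigenic 1, 3 or 5 or any WT bigenic array (0.0518 to 0.116), Fos without dNLS bigenic 2, 4 or 5 or any WT bigenic array (0.0587 to 0.209), and Ifit1 without any dNLS bigenic array or WT bigenic 1 or 2 (0.0565 to 0.138). Without WT bigenic 3 the median difference of activated microglia genes was -0.10, against -0.53 with it, at an adjusted p of 0.113, and that of interferon response genes -0.39, against -0.75. That array also stood apart for microglia genes, at a mean of 9.92, against 8.30 to 8.53 in the rest of its group. Ifit1 differed by -1.07 without WT bigenic 3, and Btg2 by -1.44 without WT bigenic 1. The activity-regulated median was -0.40, against -0.64, without dNLS bigenic 5. Meninges genes lost their call without dNLS bigenic 2 or 5 (0.0549 and 0.0656), and heat shock genes without dNLS bigenic 2 or 4 or WT bigenic 2, 3 or 4 (0.0567 to 0.0950).

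Mice with the dNLS transgene but no driver were set against nontransgenic mice to ask if the transgene acts without tTA. With limma 0 of 12394 genes passed, the smallest adjusted p being 0.841, and 196 genes had an unadjusted p under 0.05. The count was also 0 in a linear model without variance moderation. Ncapg2 changed by -0.68 ± 0.59 (n = 4 against 8, adjusted p = 1). The count was 1 without dNLS monogenic 1. In simulated data for these groups 41.8% of changes of 0.5, 76.1% of changes of 1 and 90.9% of changes of 2 log2 units were found, with 2.11% false calls. These rates hold for that simulation and do not show how many changes were missed on the real arrays. Camera passed 5 lists without any gene past the threshold, also adjusted over the list alone. Choroid plexus, striatum, glutamate receptor and synapse, and voltage-gated channel genes had medians of 0.67, 0.53, 0.21 and 0.10 (adjusted p = 4.4e-05, 0.0152, 9.7e-05 and 0.0128), and activity-regulated genes -0.29 (adjusted p = 0.0243). Each had an adjusted p of at least 0.650 with an estimated correlation, and fry passed 0 lists. Without dNLS monogenic 1 the choroid plexus median was -0.0002 (adjusted p = 0.966). The striatum median was 0.28, 0.10 and 1.44 without dNLS monogenic 1, 3 and 4, and its adjusted p was 0.194 and 0.726 without the first 2, and 0.114, 0.110 and 0.0612 without nontransgenic 3, 5 and 7. The activity-regulated median was -0.17 and -0.48 without dNLS monogenic 2 and 4, and its adjusted p was 0.497 and 0.236 without dNLS monogenic 2 and 3, and 0.0877, 0.129, 0.197 and 0.101 without nontransgenic 1, 3, 7 and 8. The glutamate receptor median was 0.11 without nontransgenic 6, and the voltage-gated channel median 0.16 and 0.07 without dNLS monogenic 2 and 4, the latter at an adjusted p of 0.224. In all, 3 lists passed without dNLS monogenic 1 or 3 or nontransgenic 3 or 7.

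Carriers of the dNLS transgene with and without the driver were compared within line NLS4. The driver is tTA, so its own effect was not separated here from that of the dNLS protein. Mthfd2, a mitochondrial folate enzyme, was 4.70-fold higher in dNLS bigenic mice, with 2.23 ± 0.44 (SE, n = 5 against 4, adjusted p = 0.00182), and Hspb3, a small heat shock protein, was higher by 2.20 ± 0.27. Ddit3, a stress transcription factor, rose by 1.17 ± 0.18. The neuropeptide Nts was lower, at -3.97 ± 1.08 (adjusted p = 0.0179), and lost its call without dNLS bigenic 1 (0.0506) or dNLS monogenic 1 (0.0684) or 3 (0.0738). Of 12394 genes 1773 passed, 962 higher and 811 lower, 168 and 132 of them by at least 2-fold. All 5 dNLS bigenic arrays lay on the side of the difference in each of the 6 named genes, which were chosen for it. Simulated differences of 0.5, 1 and 2 log2 units were found in 40.3%, 80.6% and 92.4% of cases, with 3.40% false calls.

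Camera passed 5 lists in this comparison, each lost with an estimated correlation. By fry more lists passed, as counted with the other ways of processing. Ribosomal protein genes had 16 up and 0 down of 47, and 19 and 1 adjusted over the list alone (camera adjusted p = 2.2e-07, adjusted p = 0.131 with an estimated correlation), and Rpl14 rose by 1.12 ± 0.09. Cholesterol synthesis genes had 0 up and 4 down of 15, also adjusted over the list alone (adjusted p = 0.0210, adjusted p = 0.640 with an estimated correlation), and Fdft1 fell by 0.96 ± 0.13. Deep layers genes had 0 up and 3 down of 10 and hippocampus genes 0 up and 3 down of 8, both also adjusted over the list alone (adjusted p = 0.0145 and 0.0144, adjusted p = 0.186 and adjusted p = 0.111 with an estimated correlation). RNA-binding protein genes had 1 up and 5 down of 30, and 1 and 8 adjusted over the list alone (adjusted p = 0.0210, adjusted p = 0.491 with an estimated correlation). Without dNLS monogenic 1, 8 lists passed in place of 5, and without dNLS bigenic 5 RNA-binding protein genes did not pass, at a median of -0.04 (adjusted p = 0.126). The hippocampus median of -0.04 ranged from -0.11 without dNLS monogenic 4 to -0.004 without dNLS monogenic 3, and was -0.02, -0.08 and -0.07 without dNLS bigenic 2, dNLS bigenic 4 and dNLS monogenic 2. Both groups differed in the Gapdh 3' minus middle difference, at 0.45 against 0.56 (exact permutation adjusted p = 0.0397), and dNLS monogenic 2 had a beta-actin difference of 3.13, against at most 1.72 in the rest of its group. The degraded nontransgenic arrays are in neither of these groups, but share the fitted spread and sex term. The comparison gave 2885 genes without them, among them all 1773.

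The changes of both bigenic groups were set against each other gene by gene. Of the genes that passed in both comparisons with nontransgenic mice, 42 were higher in both, 122 lower in both and 5 opposite. Independent comparisons would give 9.16, 21.9 and 30.4, but both used the same controls, which raises counts in the same direction without a shared effect. With controls split by line 1 gene passed in WT bigenic mice and 0 in both. Of the 276 genes called in WT bigenic mice 254 had the same sign in dNLS bigenic mice, at a median of 0.747 of the change relative to WT. With only NLS4 controls for dNLS bigenic mice 255 had it, at 0.789. The NLS4 controls also served for the WT bigenic calls, so the controls are still partly shared in that fit. In simulated unchanged groups that share controls, the 276 strongest WT changes had the same sign in 214 genes on average and at most 228, at a ratio of at most 0.336. Across the 9540 genes off the lowest value the log2 changes correlated with a Pearson r of 0.529 and a Spearman rho of 0.538, and genes are not independent replicates. The shared controls alone gave an r of at most 0.361 in simulations, which treat genes as independent. With the beta-actin covariate r was 0.345, below the simulated mean of 0.396 for that design, and without the 2 degraded arrays it was 0.369, against a simulated mean of 0.356 and at most 0.426. The covariance fell from 0.104 to 0.0421 and 0.0482 in these fits, against at most 0.0179 and 0.0142 in their simulations. With separate controls for each line r was 0.265, against at most 0.101 in simulations of that design.

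**Figure D5:**
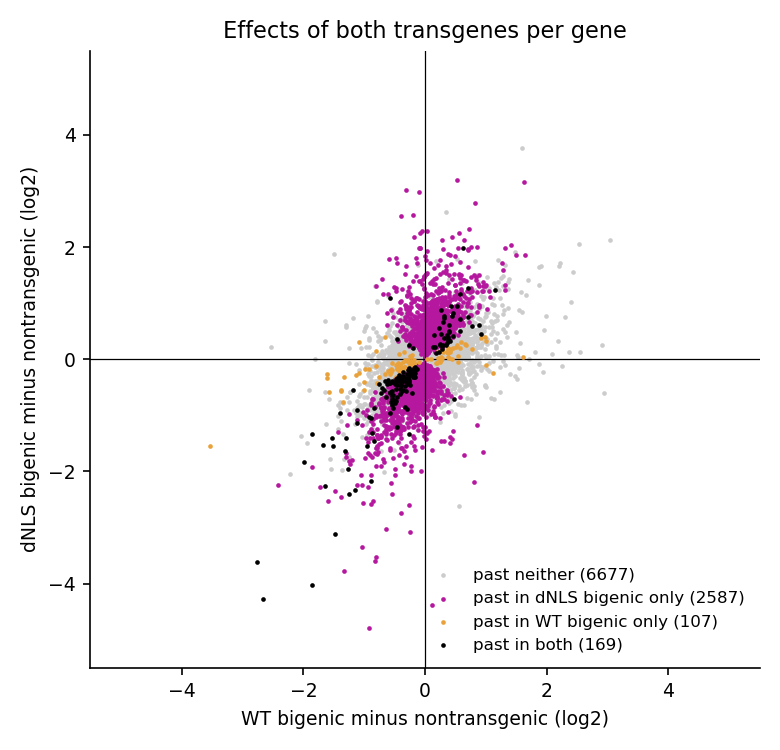
Log2 change per gene in dNLS bigenic against that in WT bigenic mice, each relative to nontransgenic, for 9540 genes. Of these 169 passed in both comparisons, 2587 in dNLS bigenic only and 107 in WT bigenic only.

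Line and sex were compared as well. Between nontransgenic mice of line NLS4 and line WT12 1 gene passed, Glb1l at -0.03 ± 0.003, and 1361 genes had an unadjusted p under 0.05 (n = 6 against 2). That count was 42 without nontransgenic 7, 21 without nontransgenic 8, 6 without nontransgenic 3 or 5, 3 without nontransgenic 6 and 2 without nontransgenic 2 or 4. Between females and males Xist, at 8.77 ± 1.05, Eif2s3y, a Y-linked translation factor, at -8.44 ± 1.02, and Kdm5d, a Y-linked demethylase, at -3.78 ± 0.49, passed, with nontransgenic 1 counted by its label. Without dNLS bigenic 5, nontransgenic 6 or WT bigenic 1 the count was 5. The interaction of sex with the dNLS transgene passed for 89 genes, 71 with sex as read from Xist and 188 without nontransgenic 6. It sets the 1 female dNLS bigenic mouse, assumed to vary like the other groups, against 4 males, so it cannot tell sex from that mouse.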

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

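The tests of RNA degradation, of WT bigenic 3 and of Ncapg2 in the same line and between bigenic groups were chosen only after the results were seen. Of 416 sets of values within a group, 66 had an array far from the others, where chance alone gives about 1 in 20 groups, or 20.8. Nontransgenic 6 was that array 23 times, WT bigenic 3 9 times, dNLS bigenic 5 8 times, dNLS monogenic 2 7 times and every other array at most 2 times.

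Nontransgenic 6 stood apart in RNA quality. Its share of probe sets at the lowest value was 30.71%, its Gapdh 3' minus 5' difference 5.04, its Gapdh 3' minus middle difference 1.82 and its correlation with the rest of its group 0.9795. Its list means lay apart for histone genes (5.86), astrocytes (11.01), hippocampus (7.12), interferon response (4.47), glutamate receptors and synapse (6.88), ALS and FTD genes (10.02) and ribosomal proteins (11.32). Its levels lay apart for Atf3 (2.24), Atf4 (11.05), Chac1 (8.56), Ctsd (11.30), Cux1 (11.09), Dach2 (5.29), Fcgr1 (3.22), H2az2 (10.54), Rplp0 (12.10), Rpp40 (7.25), Serpina3n (4.26) and Zfp54 (2.84). Other nontransgenic arrays lay apart for Arc (8.97) and Hilpda (5.81) in nontransgenic 5, Myh1 (8.30) and Tnfrsf12a (4.51) in nontransgenic 4, and Eps8l3 (2.94) and Gla (2.57) in nontransgenic 8. In dNLS monogenic 2 the beta-actin 3' minus 5' difference was 3.13, its 3' minus middle difference 1.74, the Gapdh 3' minus 5' difference 1.79, the first and second component 21.02 and 1.21, and the means of MHC class I genes 6.29 and long-intron neuronal genes 8.46. In dNLS monogenic 1 the choroid plexus mean was 6.59, and in dNLS monogenic 4 Hspb3 was 6.47.

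In WT bigenic 3 the list means lay apart for microglia (9.92), activated microglia (8.06), choroid plexus (4.64), activity-regulated genes (8.49), voltage-gated channels (8.01) and cholesterol synthesis (9.52), and the levels of Lipg (5.24), Olfml3 (11.30) and Tyrobp (11.95). WT bigenic 1 had a beta-actin difference of 1.43, and WT bigenic 4 a Gapdh 3' minus middle difference of 0.47 and an endothelium and mural cell mean of 7.81. In dNLS bigenic 5, the only female of its group, the means of histone genes (5.66), reactive astrocytes (5.08) and RNA-binding proteins (11.45) lay apart, with Elavl4 (11.28), Myh1 (3.69), Otof (2.62), Rnf207 (2.45) and Ubqln2 (12.21). Single arrays also lay apart for Atf5 (8.72) and Echdc2 (6.06) in dNLS bigenic 4, Gla (4.98) and Susd2 (2.09) in dNLS bigenic 3, and Scn3b (9.59) in dNLS bigenic 1. Among males, nontransgenic 1 stood apart with Xist at 11.97 and Eif2s3y at 2.04, and dNLS bigenic 2 with Uty at 2.91.

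A difference between groups was found for 1334 genes between dNLS and WT bigenic mice, by a test of the difference itself. The interaction of sex with the dNLS transgene passed for 89 genes, but rests on 1 female dNLS bigenic mouse and cannot tell sex from that mouse. Probe sets outside the comparisons also changed. Of 1555 without a symbol, 215 passed for dNLS bigenic against nontransgenic, 17 for WT bigenic against nontransgenic, 92 for dNLS bigenic against WT bigenic and 131 for dNLS bigenic against dNLS monogenic. Of 691 naming several symbols, 166, 22, 63 and 107 passed in the same order.

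In 4 comparisons only the real split of 100 gave as many genes, which argues against a random split of these arrays as the source of the counts. The splits cannot tell genotype from line, sex or RNA quality where these also differ between the groups. The real and the highest other counts were 2759 and 412 for dNLS bigenic against nontransgenic, 276 and 12 for WT bigenic against nontransgenic, 1334 and 600 for dNLS bigenic against WT bigenic, and 1773 and 934 for dNLS bigenic against dNLS monogenic. For sex, where the real count was 3, the highest other count was 1. For dNLS monogenic against nontransgenic the real count was 0, so all 100 splits had to give as many and nothing about chance follows. The highest other count was 920 and the median 0, and what sets the split with 920 apart was not tested. For the lists past camera chance was not excluded in any of the 5 comparisons, with 96, 84, 69, 59 and 73 of 100 splits as high. The real and highest other list counts were 1 and 13, 5 and 16, 10 and 20, 5 and 14, and 5 and 16, for dNLS bigenic and WT bigenic against nontransgenic, dNLS bigenic against WT bigenic, dNLS monogenic against nontransgenic and dNLS bigenic against dNLS monogenic.

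The large count for dNLS bigenic against nontransgenic could come from RNA degradation in the nontransgenic arrays. With the beta-actin difference as a covariate 89.89% of the changed genes still passed in the same direction, at a median of 0.903 of their change, which argues against degradation as the whole cause. For WT bigenic against nontransgenic the same covariate kept 40.94% of the 276 calls, at a median of 0.796 of their change, so degradation as a source of part of those calls stays open. Nontransgenic 1, which reads as female against its label, could have been a dNLS bigenic sample, but its position from nontransgenic at 0 to dNLS bigenic at 1 was 0.0581, within the -0.341 to 0.302 of the other nontransgenic arrays, which argues against it. A swap with a mouse outside these groups stays open, as does an effect of tTA itself.

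The higher microglia and interferon lists of WT bigenic mice may come from 1 array, WT bigenic 3. Without it the median log2 differences were 0.219 for microglia, 0.0584 for activated microglia and 0.198 for interferon response, against 0.45, 0.54 and 0.54 with it. These values neither leave nor remove the difference clearly, so 1 unusual mouse and a response of the group cannot be told apart with 4 arrays. An infection or injury of that mouse was not tested.

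An allele carried by all mice of line WT12 would lower Ncapg2 in nontransgenic mice of that line as well. WT bigenic mice differed from the 2 of these by -3.096 ± 0.838 on the log2 scale in limma (adjusted p = 0.225). The size of this difference argues against such an allele, although it did not pass the threshold. An allele that travels with the transgene would be absent from nontransgenic mice, so the comparison cannot address it and it stays open. A change that spans most of the genes beside it has no support, since the median of 14 neighbours lay at the 34.73 percentile of 9524 windows. A median over them cannot show a change limited to a few adjacent genes, so that stays open. Ncapg2 is itself in the tTA insertion locus list, whose median for WT bigenic against nontransgenic mice was -0.43, with 1 gene down. The tTA transgene, which both bigenic groups carry, could lower Ncapg2 in both, but dNLS bigenic mice were higher than WT bigenic mice by 1.99 ± 0.68 (adjusted p = 0.0752). In dNLS bigenic 1 to 3 Ncapg2 was at 6.83, 6.65 and 6.98, within the nontransgenic range of 6.63 to 8.48, and in dNLS bigenic 4 and 5 at 4.38 and 4.44. The same decrease in every tTA carrier is thus not seen, and with carriers on both sides tTA and the WT transgene cannot be told apart without mice that carry tTA alone.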

How the results depend on the processing

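The beta-actin covariate, the fit without the 2 degraded arrays, the removal of genes at the lowest value and sex as read from Xist were chosen after seeing the data. Where no reason follows from the construction of an alternative, the cause was not tested. For dNLS bigenic against nontransgenic the count of 2759 stayed within 1.5 times except at an adjusted p of 0.01 (1820), at 1.5-fold (1158), which are stricter, and with array weights (4241). For WT bigenic against nontransgenic the 276 genes became 2 at 0.01, 75 at 1.5-fold, 505 without the sex covariate, 4965 with centred arrays, 878 with array weights, 0 with only the 2 groups in limma, 1 with controls of the same line, 1 in females only, 163 with the beta-actin covariate and 424 without the degraded arrays. The fits with only 2 groups, with the same line and with females held fewer arrays. The 1334 genes of dNLS bigenic against WT bigenic became 690, 610, 3120 with array weights, 2320 with only the 2 groups, 440 with controls of the same line, 2437 with the covariate and 2274 without the degraded arrays, the first 2 at 0.01 and 1.5-fold. The 1773 genes of dNLS bigenic against dNLS monogenic became 1098 and 803 in the same way, 4296 with weights, 2890 with the covariate and 2885 without the degraded arrays. The line count of 1 became 2 with the covariate, the sex count of 3 became 0 in limma without the sex label check genes, which are the genes it held, and the interaction count of 89 became 305 without the degraded arrays and 71 with sex as read from Xist. Sex as read from Xist gave 2691, 413, 1320, 0 and 1784 genes in the 5 comparisons, and 4 for sex.

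Leaving out single arrays gave 2365 to 3316 genes for dNLS bigenic and 37 to 579 for WT bigenic against nontransgenic, 817 to 1301 for dNLS bigenic against WT bigenic, 0 to 1 for dNLS monogenic against nontransgenic and 1373 to 1683 for dNLS bigenic against dNLS monogenic. It gave 1 to 42 for line, 3 to 5 for sex and 68 to 188 for the interaction. Lists past camera ranged over 1 to 6, 5 to 7, 8 to 11, 3 to 6 and 5 to 8 in the same 5 comparisons. Except for sex, only arrays of the compared groups were left out singly, so these are not ranges over all 21 arrays. Without both degraded nontransgenic arrays, dNLS bigenic mice gave 2274 genes against WT bigenic and 2885 against dNLS monogenic mice, above the ranges given here. The choroid plexus median for dNLS monogenic against nontransgenic ranged from -0.0002066 without dNLS monogenic 1 to 0.96. With an estimated correlation 0 lists passed in each comparison. Fry passed 12 for dNLS bigenic and 1 for WT bigenic against nontransgenic, 0 for dNLS monogenic against nontransgenic and 11 for dNLS bigenic against dNLS monogenic. Without the degraded arrays 3 lists passed for dNLS bigenic against nontransgenic, and with the covariate 6, with 14 for WT bigenic against nontransgenic and 9 for dNLS bigenic against dNLS monogenic. With controls of the same line 15 passed for WT bigenic against nontransgenic and 5 for dNLS bigenic against WT bigenic. The correlation of both effects was 0.265 with controls split by line, 0.649 over genes past the threshold in either, 0.369 without the degraded arrays and 0.345 with the covariate.

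Tardbp depended on the probe set. The dimmest gave 1.11 for dNLS bigenic and 0.48 for WT bigenic against nontransgenic, 0.63 for dNLS bigenic against WT bigenic, 0.28 for dNLS monogenic against nontransgenic and 0.83 for dNLS bigenic against dNLS monogenic. The third in mean gave -0.43, 0.0122 and 0.22 against nontransgenic in dNLS bigenic, WT bigenic and dNLS monogenic mice, and the second -1.11 and -1.10 for dNLS bigenic against WT bigenic and dNLS monogenic. Other probe sets also lost or turned the sign for Cars (-0.0230), Cux1 (7.2e-05), Elavl4 (0.14), Mef2c (0.10 and 1.31), Myh1 (0.005742) and Scn3b (0.0149), and gave 0 for Aldh1l1, Atf4, Fdft1 (2 probe sets), Gla, Rora, Tle4 and Ubqln2, all for dNLS bigenic against nontransgenic. For WT bigenic against nontransgenic they gave 0 for Lipg, Rgs16 and Rpf1 and 7.2e-05 for Ngb, and for dNLS bigenic against dNLS monogenic 0 for both of Fdft1. Values of 0 are those of probe sets at the lowest value, where a change cannot be read. Genes that the rule named past the threshold for dNLS bigenic against nontransgenic had 83 other probe sets. Of these 19 passed in the same direction and 1, of Tardbp, in the opposite one. In the same direction 1 of 24 passed for WT bigenic against nontransgenic, 15 of 46 for dNLS bigenic against WT bigenic, and 15 of 52 against dNLS monogenic. Of the other alternatives for single genes, lists and quality measures, 826 kept direction and side of the threshold, 143 lost the threshold and 1 gained it, and with single arrays left out 1613 kept both, 152 lost the threshold and 3 gained it. Males only was not run for WT bigenic mice, with 1 male, nor females only for dNLS bigenic or dNLS monogenic mice, with 1 female each.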

Other observations

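Of the tests in this part, the comparisons of Prnp were chosen after their result was seen. The set of aminoacyl-tRNA synthetases was chosen after Cars was seen among the largest increases, but before the set itself was tested. Cars, the cytoplasmic cysteinyl-tRNA synthetase, was among the largest increases in dNLS bigenic mice, and 11 of 17 other aminoacyl-tRNA synthetases, enzymes that load amino acids on tRNA, rose as well. The other 6 did not pass, among them Farsb and Gars with changes of -0.07 and -0.05, and 0 fell. The set had a median change of 0.55 on the log2 scale, against 0.06 for WT bigenic against nontransgenic. Kars, Rars and Wars rose by 0.76 ± 0.06, 0.80 ± 0.12 and 0.49 ± 0.04. Camera gave the set an unadjusted p = 3.0e-09, and an unadjusted p = 0.004956 with an estimated correlation. The gene lists above were adjusted over the lists of a comparison, so these values cannot be set beside theirs. A shift of these genes as a set is a candidate explanation for the place of Cars. It is a hypothesis found and tested on the same arrays.

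In limma 2 probe sets of Prnp, the prion protein gene, were higher in dNLS bigenic than in nontransgenic mice. They differed by 0.38 ± 0.04 (adjusted p = 1.2e-06) and 1.75 ± 0.34 (adjusted p = 0.0013). Prnp was chosen after its values were seen. Neither the sequences of the probe sets nor the regulatory sequence of the transgenes was analysed here. A change of the mouse gene was thus not told apart from signal of the transgenes.

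Changed genes that lie next to each other and move the same way could follow from variants or transgenes linked to them. For dNLS bigenic against nontransgenic there were 468 such pairs, against a median of 397 and at most 456 in 10000 shuffles, at a permutation p = 1e-04, the smallest they can give. Neighbouring genes that share regulation would give the same excess, and this was not tested. For WT bigenic against nontransgenic there were 2 pairs, against a median of 4 (permutation p = 0.940). This shows no excess there. With so few pairs a linked change of a few adjacent genes could not be seen, so that stays open.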
